A study of Rattus norvegicus with 72 samples.

How the data were processed

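Total RNA of rat lung was extracted and 200 ng was labelled with a low-input kit for 2 colours, per the labels' protocols. The lung RNA carried Cy3 and a commercial rat reference, a pool of 14 cell types, carried Cy5 on all 72 arrays, per the labels. The authors deposited 1 log2 ratio per probe and array, in a table of 41012 Agilent probes. The log base is taken from the range of the deposited values, -9.31 to 9.93, which is too wide for log10; a natural log is not excluded by that range. The scanner, background correction, normalization, centring and the direction of the ratio are not given in the sources used here. No value was missing or exactly 0, and no probe was listed more than once. Array medians lay from 0.00252 to 0.0118. All pairs of arrays correlated positively, with a lowest r of 0.841 and a median of 0.973 within groups, so all arrays run the same way. Because intensities were not used here, neither background nor saturation could be judged, and a normalization that compresses ratios would make differences smaller.

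Groups came from the treatment and time in the labels: 35 bleomycin, 34 vehicle and 3 untreated animals in 15 groups. The series text gives 5 animals per group, so replicates are separate animals. A vehicle replicate 3 at 2 weeks was not analysed here. The labels give no slide or date, so array batches could not be tested. The smallest SD of the difference between arrays of a group was 0.175, so no pair held the same values. No column outside these samples was used.

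All comparisons, alternatives and the rule for named items were fixed before the data were examined, except where stated otherwise. The plan assumed genes, with the probes of a gene averaged. No table pairing these probes with genes was used here, so each probe was tested on its own, and the planned gene panel, the gene lists, their set tests and the check of direction from marker genes were not run. The rule named, at every time, the items with the largest rise and fall among those called whose bleomycin and vehicle animals do not overlap. It also named items from the tests over time, from the vehicle comparisons and among those called at all times. It is limited here to 2 probes in each direction, since probe identifiers carry no gene name.

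One mean per group was fitted to the deposited log2 ratios of all 72 arrays with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 57 residual and 1.13 prior degrees of freedom. All groups share 1 estimate of the spread per probe. Contrasts were bleomycin minus vehicle at each time, the F test of treatment by time, each time against 1 week, vehicle minus untreated, the F test over vehicle groups, and the mean effect. Probes were called at a Benjamini-Hochberg adjusted p under 0.05 over all probes. The procedure was tested on simulated data for the comparison at 1 week, with 200 of 41012 probes changed. It recovered 78% of the probes changed by 0.5 and 96% of those changed by 1 on the log2 scale, and 10 of its 184 calls were false. The simulated noise was independent between probes and equal in size on all arrays. Real arrays had weights from 0.286 to 1.94, so this share of false calls need not hold for them.

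The response score, the overlaps between times, the pairs of vehicle groups and the grouping of probes by level were chosen after the data were examined. For each time, probes were chosen from a fit without the animals of that time, as those with a called mean effect over the other 6 times of at least 2-fold. The sets held 88 to 154 higher and 25 to 51 lower probes. Scores were compared with 2-sided exact permutation tests in scipy 1.17.1 under Python 3.11.15, with Benjamini-Hochberg adjustment over 8 comparisons. Figures were drawn with matplotlib 3.10.9.

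Alternatives were quantile normalization, median centring, the probes with the larger interquartile range, trend and robust moderation, array weights, the replicate number as a block, a fold change of at least 2, only the groups compared, pooled vehicle animals, untreated animals as controls, and each animal left out in turn. A division of each array by its slope and a covariate for the main axis of within-group deviations were added after the data were examined.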

Results

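Lung RNA was measured in 72 rats on 2-colour arrays. Each array set the lung RNA of 1 animal, labelled with Cy3, against a common reference labelled with Cy5, a pool of 14 rat cell types. Bleomycin is an anticancer drug that injures the lung and is used to produce pulmonary fibrosis in rodents. Rats given bleomycin and rats given the vehicle were compared at 3 days and at 1, 2, 3, 4, 6 and 8 weeks. Each group held 5 animals, except the vehicle group at 2 weeks with 4, and 3 untreated rats were examined at 3 days. Values were present for 41012 probes on every array, with array medians from 0.00252 to 0.0118. The number of arrays limits the precision. The files do not pair the probes with gene names, so results are given for probes. Values are taken as log2 ratios. Whether a higher value stands for more lung RNA or more reference RNA was not settled, so "higher" and "lower" describe the deposited value and not expression.

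At 3 days, 9944 probes (24.2%) differed between bleomycin and vehicle animals at an adjusted p under 0.05 (limma, n = 5 and 5). The value was higher after bleomycin for 4977 of them and lower for 4967. A difference of at least 2-fold was seen for 579 higher and 406 lower probes. At 1 week, 8568 probes differed, 4288 higher and 4280 lower, with 442 and 305 of them by at least 2-fold. At 2 weeks, 5795 probes differed, 3031 higher and 2764 lower, with 415 and 190 by at least 2-fold (n = 5 and 4). The counts past 2-fold rest on the log2 scale: if the values were natural logs, 2509 probes would pass 2-fold at 3 days in place of 985, 1770 in place of 747 at 1 week and 225 in place of 65 at 8 weeks. Of the probes called at 1 week, 4855 had bleomycin and vehicle animals that did not overlap. Over all probes, 13.2% did not overlap at 1 week, against 0.794% from chance for 5 against 5. When only the 2 groups compared entered the fit, 6602 probes were called at 3 days, and with all vehicle animals pooled as the control 15482 were called at 3 days and 12978 at 1 week.

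**Figure D1:**
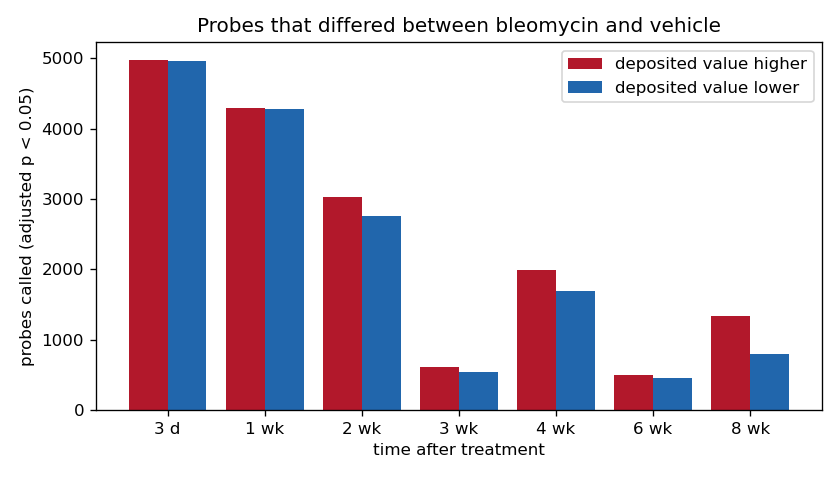
Number of probes (vertical axis) called at an adjusted p under 0.05 between bleomycin and vehicle animals at each time (horizontal axis), with bars for probes whose deposited value was higher and lower after bleomycin. The bars stand at 4977 and 4967 probes at 3 days and at 613 and 543 probes at 3 weeks.

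The probes with the largest differences at 1 week and no overlap between animals followed this course; their choice at 1 week enlarges the differences at that time. Probe A_43_P11590 had a value of 3.93 ± 0.65 (SD, n = 5) after bleomycin and -0.46 ± 0.19 (SD, n = 5) after vehicle at 1 week, a difference of 4.39 ± 0.31 (SE) on the log2 scale (limma, adjusted p = 4.6e-17). Its difference was 3.89 at 3 days, 3.73 at 2 weeks, 1.43 at 3 weeks and 1.29 at 4 weeks. At 6 and 8 weeks it was 0.67 and 0.91, which did not pass the test (limma, adjusted p = 0.30 and 0.069). Probe A_43_P11590 at 8 weeks passed the test at 1.35 when vehicle replicate 2 was left out and at 1.20 when bleomycin replicate 4 was left out. Probe A_43_P15489 stood at -2.50 ± 0.37 (SD, n = 5) after bleomycin and -6.55 ± 0.32 (SD, n = 5) after vehicle at 1 week. Its difference was largest at 3 days, at 4.99 ± 0.27 (SE), and was 4.05 at 1 week, 2.98 at 2 weeks, 1.06 at 3 weeks and 1.09 at 4 weeks. At 6 and 8 weeks the difference of A_43_P15489 was 0.59 and 0.61 and did not pass (limma, adjusted p = 0.29 and 0.18). Without vehicle replicate 2 it was 0.87 at 8 weeks and passed, and the call at 4 weeks ended when only the 2 groups compared entered the fit.

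Probe A_44_P1004757 was lower after bleomycin at 1 week, at -2.68 ± 0.93 (SD, n = 5) against 1.25 ± 0.18 (SD, n = 5), a difference of -3.93 ± 0.28 (SE). The difference of A_44_P1004757 was -2.69 at 3 days and -3.16 at 2 weeks, and at 6 and 8 weeks it was 0.04 and 0.28 and did not pass the test (limma, adjusted p = 1.0 and 0.67). It was lower by 2.01-fold at 3 weeks and 1.86-fold at 4 weeks, which passed narrowly (limma, adjusted p = 0.035 and 0.034). Quantile normalization ended both calls, at -0.96 and -0.84. The call at 3 weeks also ended without bleomycin replicate 2 or 5 or any of vehicle replicates 1 to 4, at -1.02 to -0.85, and that at 4 weeks without bleomycin replicate 2, 3 or 5 or vehicle replicate 1, 2, 3 or 5, at -0.93 to -0.80. Probe A_44_P829197 was lower by -2.33 at 3 days, -2.98 ± 0.27 (SE) at 1 week and -2.69 at 2 weeks. From 3 weeks on, the differences of A_44_P829197 were -0.45, -0.58, 0.59 and 0.46 and did not pass (limma, adjusted p from 0.18 to 0.49). The difference of 0.59 at 6 weeks passed when only the 2 groups compared entered the fit.

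**Figure D2:**
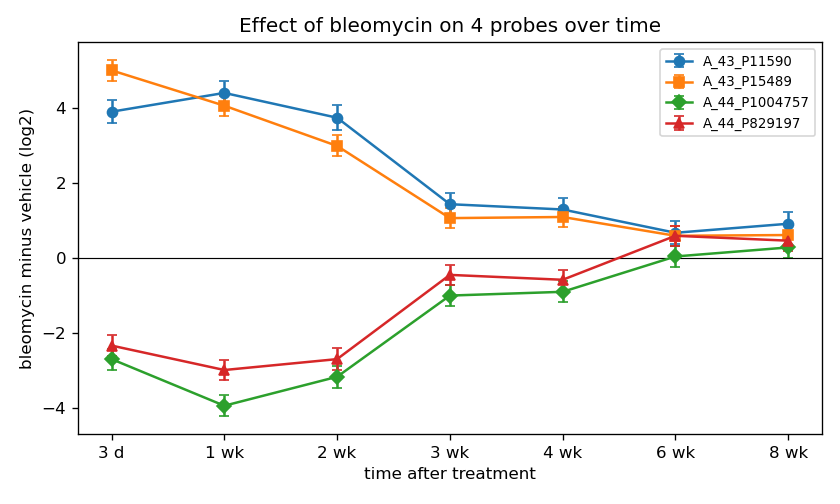
Difference between bleomycin and vehicle animals on the log2 scale (vertical axis, points with standard error) at each time (horizontal axis) for 4 probes. The differences at 1 week are 4.39 and 4.05 for the probes that were higher and -3.93 and -2.98 for those that were lower, and at 8 weeks they lie between 0.28 and 0.91.

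At 3 weeks, 1156 probes differed, 613 higher and 543 lower, and 85 of them by at least 2-fold (limma, n = 5 and 5). Without bleomycin replicate 2 the count at 3 weeks was 744, with array weights it was 2173, and with pooled vehicle animals 3817. At 4 weeks, 3681 probes differed, 1989 higher and 1692 lower, with 150 by at least 2-fold. At 6 weeks, 962 probes differed, 502 higher and 460 lower, with 60 by at least 2-fold. The counts at 4 and 6 weeks were 5753 and 2779 with array weights and 2229 and 1591 when only the 2 groups compared entered the fit. At 6 weeks the count was 2345 with pooled vehicle animals and 1541 with the covariate for within-group deviations. At 8 weeks, 2124 probes differed, 1330 higher and 794 lower, with 65 by at least 2-fold. The count at 8 weeks was 203 when only the 2 groups compared entered the fit, 1301 without bleomycin replicate 2, 1404 without bleomycin replicate 5, 1377 after quantile normalization and 4782 with pooled vehicle animals.

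The time course asks how the effect of bleomycin changed after the early weeks. The effect differed over time for 7161 probes (limma F test of the treatment by time terms). The 442 probes that were at least 2-fold higher at 1 week had a median difference of 1.20 at 3 days, 1.29 at 1 week and 1.18 at 2 weeks. Their median was 0.39 at 3 weeks, 0.48 at 4 weeks, 0.27 at 6 weeks and 0.12 at 8 weeks. The 305 probes that were at least 2-fold lower at 1 week had medians of -1.11, -1.22 and -0.91 at 3 days, 1 week and 2 weeks, and of -0.41, -0.57, -0.29 and -0.24 at 3, 4, 6 and 8 weeks. These probes were chosen at 1 week, which enlarges their medians at that time. Without vehicle replicate 2 at 8 weeks, the medians at 8 weeks were 0.25 and -0.33.

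Against 1 week, the effect differed for 725 probes at 3 days, 92 at 2 weeks, 2047 at 3 weeks, 1439 at 4 weeks, 2602 at 6 weeks and 4973 at 8 weeks, each tested as the difference itself with limma. The effect was smaller than at 1 week for 79.9% of the 4973 probes at 8 weeks and for 89.0% of the 2047 probes at 3 weeks. At 3 days it was smaller for 33.2% of the 725 probes. The count at 2 weeks was 141 without vehicle replicate 3 of 1 week, and the counts at 3 days and 2 weeks were 1346 and 152 after quantile normalization. At 4 weeks the count was 2709 with array weights and 2367 with the covariate for within-group deviations. For the 725 probes at 3 days, 5 of 100 splits of the samples gave as many, so chance is not excluded.

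Probes called at 1 week were compared with those of other times, each time having its own vehicle animals. Of the 4288 probes higher at 1 week, 2577 were also higher at 3 days, where independent lists would share 520.4, and 2090 were higher at 2 weeks, where they would share 316.9. At 8 weeks 249 of them were higher, against 139.1 for independent lists, and 69 were lower. Of the 4280 probes lower at 1 week, 221 were lower at 8 weeks, against 82.9, and 77 were higher. Across probes, which are not independent replicates, the effects of 1 week correlated with those of 3 days at r = 0.78, of 2 weeks at 0.79, of 4 weeks at 0.59 and of 8 weeks at 0.22. Without vehicle replicate 2 of 8 weeks, the correlation of 1 week with 8 weeks was 0.35. At all 7 times, 40 probes were higher and 30 were lower. These counts were 80 and 63 without vehicle replicate 2 of 8 weeks. The 40 probes had median differences from 0.66 at 8 weeks to 1.40 at 2 weeks. The mean effect over the 7 times was called for 15324 probes, 7843 higher and 7481 lower, of which 153 passed 2-fold.

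A response score per animal was taken as the mean value of the probes that were higher after bleomycin minus that of the lower probes, with the probes chosen from the other 6 times. It was -0.03 ± 0.48 (SD, n = 5) in bleomycin animals at 1 week and -3.51 ± 0.18 (SD, n = 5) in vehicle animals, a difference of 3.48. The difference was 2.29 at 3 days, 3.71 at 2 weeks, 1.68 at 3 weeks, 2.16 at 4 weeks, 1.23 at 6 weeks and 0.96 at 8 weeks. Each time has its own set of probes, 88 higher and 25 lower at 1 week but 154 and 51 at 8 weeks. Scores of different times are therefore not the same measure. In a 2-sided exact permutation test the p was 0.00794 at 3 days and at 1, 3, 4 and 6 weeks, and 0.0159 at 2 weeks, each the smallest the groups allow. At 8 weeks the exact permutation p was 0.0476. Adjusted over the 8 comparisons of scores, the exact permutation p was 0.0127 at those 5 times, 0.0212 at 2 weeks and 0.0476 at 8 weeks. Every bleomycin animal lay above every vehicle animal of its time except at 8 weeks, where vehicle replicate 2 had a score of -1.96 and the bleomycin animals lay between -2.70 and -1.97. Without that animal the difference at 8 weeks was 1.27 (exact permutation p = 0.0159, the smallest possible). It was the only vehicle animal that overlapped, so leaving it out fixed this p in advance, and the p adds no support.

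**Figure D3:**
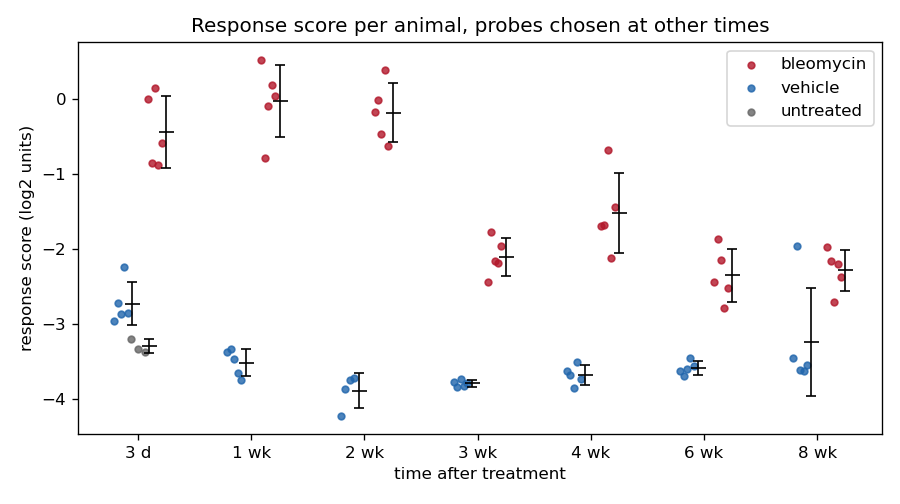
Response score in log2 units (vertical axis) of each animal at each time (horizontal axis), with points for bleomycin, vehicle and untreated animals and the mean with SD of each group. The probes of the score differ between times. At 1 week the bleomycin animals lie between -0.79 and 0.52 and the vehicle animals between -3.75 and -3.33, and at 8 weeks a vehicle animal lies at -1.96.

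At most times, bleomycin values lay closer to 0 than vehicle values for probes far from 0 on either side. Across probes, the effect correlated with the vehicle level of the other times at -0.43 at 3 days and -0.45 at 1 and 2 weeks. Pairs of vehicle groups gave -0.22 to 0.33. At 3 and 6 weeks the correlation was -0.20 and -0.12, inside that range. At 4 and 8 weeks it was -0.32 and -0.28, below the range but no larger in size than its upper end. At 1 week, probes with a vehicle level under -3 at the other times were higher by a median of 0.355, and probes with a level over 3 were lower, with a median of -0.340. Of the 640 probes under -3, 310 were called higher and 7 lower. Of the 595 probes over 3, 238 were called lower and 38 higher. At 3 weeks the medians at the low and high ends were 0.069 and -0.049. At 6 weeks this did not hold at the high end, where the 603 probes over 3 had a median of 0.060, with 15 called higher and 11 lower. The slope of an array on the mean vehicle profile was 0.814 ± 0.0270 (SD, n = 5) for bleomycin at 3 days, 0.858 ± 0.0317 at 1 week, 0.897 ± 0.0255 at 2 weeks and 0.963 ± 0.0153 at 8 weeks. It was 0.960, 0.947 and 0.974 at 3, 4 and 6 weeks. Vehicle groups had mean slopes from 0.962 to 1.02. They make up the profile, so their slopes average 1 by construction and are no independent baseline. Untreated animals, outside that profile, had 0.977, against 0.814 to 0.974 in the bleomycin groups.

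**Figure D4:**
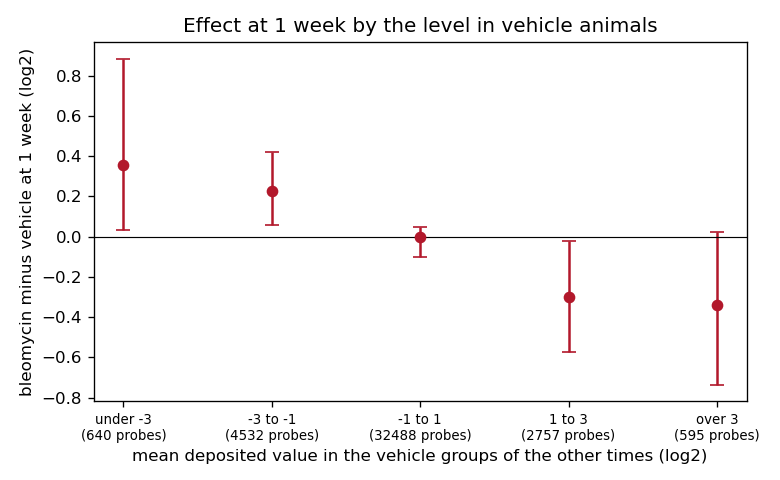
Difference between bleomycin and vehicle animals at 1 week on the log2 scale (vertical axis) for probes grouped by their mean value in the vehicle groups of the other times (horizontal axis, log2), with points for the median and bars for the quartiles. The medians go from 0.355 for the 640 probes under -3 to -0.340 for the 595 probes over 3.

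The untreated rats allow the vehicle treatment itself to be examined at 3 days. Vehicle animals differed from untreated animals for 795 probes, 238 higher and 557 lower, of which 17 passed 2-fold (limma, n = 5 and 3). The largest differences were 1.45 and -1.55. The response score was -2.72 ± 0.29 (SD, n = 5) after vehicle and -3.29 ± 0.09 (SD, n = 3) in untreated animals, a difference of 0.57 (2-sided exact permutation p = 0.0357, the smallest possible, 0.0408 adjusted). As many probes were called by 3 of 56 splits of these 8 animals, so chance is not excluded for this count. The count of 795 was 15 when only the 2 groups compared entered the fit, where 13.3% were higher against 29.9% above. It was 269 and 511 without vehicle replicates 1 and 2, and 414, 421 and 275 without untreated replicates 1, 2 and 3. It was higher, at 1061, without vehicle replicate 3, at 1199 with array weights, at 1420 with the replicate number as a block and at 2492 with the covariate.

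The vehicle groups differed over time for 5303 probes (limma F test). Vehicle animals at 3 days differed from those of later times for 590 probes at 1 week and for up to 6262 at 6 weeks. Among the times from 1 week on, pairs of vehicle groups differed for 3 to 494 probes. The count over time was 10289 with array weights, 9672 with the covariate and 4144 without vehicle replicate 1 of 3 days.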

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

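The tests of shrunken arrays and of 1 factor at every level, of regression to the mean, swapped labels, a wrong label, a shared deviation and recovery were chosen after the patterns were seen. For the probes called both before and after division by the slope, a shared deviation and recovery, the deciding values were set before the test was run.

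Vehicle replicate 2 at 8 weeks had a response score of -1.96, far from the other 4 vehicle animals at -3.62 to -3.44. Probe A_43_P11590 also stood apart in that animal, at 1.98 against -0.33 to -0.08. A swap with a bleomycin animal of 8 weeks would leave a bleomycin animal among the vehicle scores, but the lowest bleomycin score lay 0.747 above the highest of the other 4 vehicle scores. The main axis of deviations within groups of other times is also argued against as the source of the gap in score. After that axis was removed 100.3% of the gap stayed, a step that took away 23.2% of this animal's squared deviation. The step took away 9.89% of the within-group variance of the 8-week arrays. Deviations shared along other axes were not examined and stay open. A lung of a bleomycin animal under a vehicle label cannot be told apart from other causes: the slope of its profile on the effect at 8 weeks was 0.267, under the range of 0.339 to 0.641 of the bleomycin animals but by 0.0721, less than their SD of 0.110. Its correlation with the effects at 3 days and 1 week was 0.47 and 0.46, above the bleomycin animals of 8 weeks at 0.11 to 0.33 and 0.15 to 0.34, but with the effect at 4 weeks it was 0.20, below their 0.26 to 0.47; no biological explanation was tested.

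The effect of bleomycin differed over time for 7161 probes by the test of the difference itself. Of 100 splits of the samples, 1, the real one, gave as many, with 493 in the highest other split. These splits shuffled the treatment labels within each time. They take away the effect itself and not only its change, so they cannot exclude chance for a change over time, here or against 1 week. Against 1 week, the effect differed for 2047 probes at 3 weeks, 1439 at 4 weeks, 2602 at 6 weeks and 4973 at 8 weeks. In each of these comparisons 1 of 100 splits gave as many, and the highest other splits gave 2, 2, 8 and 17 probes. The difference of 2 weeks from 1 week was called for 92 probes, and 2 of 100 splits gave as many, with 549 in the highest other split. The difference of 3 days from 1 week was called for 725 probes, but 5 of 100 splits gave as many, with 1815 in the highest, so chance is not excluded. Splits that call several times the real count may point to a structure of the samples. Some arrays stood apart along the main axis of within-group deviations, after bleomycin as well as vehicle. Among them, bleomycin replicate 1 at 3 days lay at 0.254 and bleomycin replicate 4 at 4 weeks at 0.198. Vehicle replicate 2 at 8 weeks lay at 0.286. Vehicle replicate 1 at 3 days lay at 0.364, against -0.1625 to 0.075 for the rest of its group. Vehicle replicate 3 at 1 week lay at 0.353, against -0.0922 to -0.0855. At 4 weeks, vehicle replicates 1 and 2 lay at 0.179 and 0.155, and replicates 4 and 5 at -0.192 and -0.1999. Whether this axis accounts for such splits was not tested. Of the named probes, A_43_P11590 and A_43_P15489 had effects at 8 weeks that differed from those at 1 week by -3.48 and -3.44, and A_44_P1004757 and A_44_P829197 by 4.22 and 3.44 (limma). These probes were chosen for large effects at 1 week, so part of each difference is built in by that choice.

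Other single animals stood apart from their group in the named probes or the array median. For A_43_P11590 these were vehicle replicate 4 at 3 days, at 0.90 against -0.49 to -0.22, and vehicle replicate 4 at 4 weeks, at 0.44 against -0.48 to -0.37. The latter animal stood apart for A_43_P15489 too, at -5.07 against -6.53 to -6.15. For A_44_P829197 they were bleomycin replicate 5 at 8 weeks at 3.49, vehicle replicate 1 at 2 weeks at 2.06, vehicle replicate 1 at 3 weeks at 3.32 and vehicle replicate 2 at 6 weeks at 2.99. The array median of bleomycin replicate 4 at 4 weeks was 0.00958, against 0.00448 to 0.00517. The criterion was Dixon's ratio, the gap of the extreme value to the next over the range of the group. In all, 10 of 84 groups of values held such an animal, where chance gives about 1 in 20 for a single group. The 84 groups take the same animals on several measures and are not independent, so an excess over chance is not shown.

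At 1 week, values after bleomycin lay closer to 0 on both sides of 0; at 6 weeks probes over 3 did not, with a median of 0.060. After each array was divided by its slope, 71.9% of the probes called at 1 week were called again, in either direction. This argues against shrinkage by 1 factor as the whole account of the calls, but does not show that they kept their direction. For the pattern itself, such a factor at every level is argued against because 3 of 4 level groups away from 0 were not brought level: both ends turned sign and lay farther from 0 than vehicle, by -0.220 under -3 and 0.275 over 3, while probes from 1 to 3 stayed toward 0, by -0.107. Regression to the mean is argued against too: the effect at 1 week correlated with the vehicle level of other times at -0.45, while pairs of vehicle groups gave -0.22 to 0.33. Shrinkage as part of the pattern, compression that acts unevenly over probes and a change in the cells that make up the lung after bleomycin stay open and were not tested.

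The vehicle groups differed over time for 5303 probes, which 1 of 100 splits reached, with 3077 in the highest other split. Recovery from the vehicle treatment would place untreated animals with the later vehicle animals. On a scale from 0 at vehicle of 3 days to 1 at the later vehicle group, they lay at a median of 0.43, from 0.36 to 0.64 over the 6 later times as means of 10 splits of the vehicle animals of 3 days. Single splits ranged from -0.02 at 4 weeks to 0.73 at 1 week. Recovery cannot be told apart from age or array batch, since untreated animals were measured at 3 days alone and their position varied this much between splits.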

How the results depend on the processing

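Leaving out animals, and all alternatives but the last 2, were planned; the division by slope and the covariate were chosen after the results were seen. Where a named probe was called, its sign held under every alternative run. Which of higher and lower calls were more numerous turned in 27 counts under other alternatives and in 15 with an animal left out, mostly where the shares were close to even. Division by the slope moved the share of higher calls from 50.1% to 42.2% at 3 days, from 50.1% to 45.0% at 1 week, from 52.3% to 45.9% at 2 weeks and from 51.2% to 45.3% for the mean effect. Of the counts, 123 stayed within 1.5 times the reported count under an alternative and 44 did not. Median centring, trend and robust moderation and the probes with the larger interquartile range moved no count that far. Untreated controls were run for the count at 3 days alone, which became 10335. The cause was not tested except where given. Quantile normalization gave 1377 probes at 8 weeks, and 1346 at 3 days and 152 at 2 weeks for the difference from 1 week. Array weights gave 2173 at 3 weeks, 5753 at 4 weeks, 2779 at 6 weeks, 194 and 2709 for 2 and 4 weeks against 1 week, 1199 for vehicle against untreated and 10289 for the vehicle groups over time. A fold change of at least 2, which calls fewer probes by construction, gave 985, 747, 605, 85, 150, 60 and 65 at the 7 times. It gave 113, 44, 364, 295, 520 and 662 against 1 week, 17 for vehicle against untreated and 153 for the mean effect. With only the groups compared, the counts were 6602 at 3 days, 2229 at 4 weeks, 1591 at 6 weeks, 203 at 8 weeks and 15 for vehicle against untreated. Pooled vehicle animals gave 15482 at 3 days, 12978 at 1 week, 3817 at 3 weeks, 2345 at 6 weeks and 4782 at 8 weeks. Division by the slope gave 1535 and 154 for 3 days and 2 weeks against 1 week. The covariate, which lowers the residual spread by construction, gave 1541 at 6 weeks, 1166, 151 and 2367 for 3 days, 2 and 4 weeks against 1 week, 2492 for vehicle against untreated, with 42.3% higher against 29.9%, and 9672 for the vehicle groups over time.

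Of the named probes at 8 weeks, A_43_P11590 and A_43_P15489 passed the test with array weights, at 1.24 and 0.88, and with pooled vehicle animals, at 1.35 and 0.68. The former also passed at 0.91 among the probes with the larger interquartile range. Division by the slope ended the calls of A_44_P1004757 at 3 and 4 weeks, at -1.01 and -0.87.

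The replicate number as a block gave 1420 probes for vehicle against untreated and changed no other count by over 1.5 times. This block was shared over all times, so it could not test pairing within a time. No pairing by number was seen over all times. Of 34 same-numbered pairs of bleomycin and vehicle animals, 11 had deviations that correlated above 0.1, and at no time did every pair. At 3 days 4 of 5 pairs did, at 0.06 to 0.51 over the 5. Along the main axis of within-group deviations, replicate 1 of 3 days lay at 0.254 after bleomycin and 0.364 after vehicle. Replicate 5 lay at -0.127 and -0.1625. A structure tied to the replicate number at 3 days therefore stays open. In all, 8 of 34 bleomycin arrays correlated best with the vehicle array of their own number.

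Leaving out 1 animal moved the count at 3 weeks between 744 and 1324, at 8 weeks between 1301 and 2285, for 2 weeks against 1 week between 71 and 141, and for vehicle against untreated between 269 and 1061. The other counts stayed within 1.5 times the reported count, such as 8785 to 10061 at 3 days, 7483 to 8492 at 1 week, and 547 to 879 and 1098 to 1819 for 3 days and 4 weeks against 1 week. Alternatives on the probes of a gene, on gene lists and on direction from marker genes were not run, as no gene names were used here. The filter on missing values changes nothing, since no value was missing. Without intensities, the signal over background that limits each probe is unknown.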

Other observations

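The test of direction was chosen after the result was seen.

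Between 1 and 8 weeks the probes called changed as well as their number. The difference between the times was called for 553 probes that were called at 8 weeks and not at 1 week, 375 higher and 178 lower at 8 weeks. Without vehicle replicate 2 of 8 weeks this count was 474. Of all probes, 16769 were called at 1 or more times, 8502 of them at 1 time alone, and 486 were higher at 1 time and lower at another. The probes lower after vehicle than in untreated animals numbered 557, of which 140 were also lower after bleomycin at 1 week, where independent lists would share 58.1, and 25 went the other way, against 58.2. Of the 557, 113, 33, 83 and 32 were lower at 2, 3, 4 and 6 weeks, against 37.5, 7.4, 23 and 6.2. The other way went 23, 3, 27 and 0, against 41.2, 8.3, 27 and 6.8. At 8 weeks 7 of the 557 were lower, against 10.8, and 16 went the other way, against 18.1. Of the 238 probes higher after vehicle, 41 were higher after bleomycin at 1 week, against 24.9, and 32 went the other way, against 24.8, so both directions exceeded independent lists at that time. At 2, 3, 4 and 6 weeks 29, 14, 16 and 10 were higher, against 17.6, 3.6, 11.5 and 2.9. The other way went 15, 3, 10 and 0, against 16, 3.2, 9.8 and 2.7. At 8 weeks 7 were higher, against 7.7, and 10 went the other way, against 4.6.

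Some whole arrays of vehicle groups stood apart. Vehicle replicate 1 at 3 days had a mean correlation of 0.941 with the other arrays of its group, where they had 0.961 to 0.967, and an array weight of 0.306. Vehicle replicate 3 at 1 week had 0.955, against 0.971 to 0.975, and a weight of 0.442. At 8 weeks, vehicle replicates 1 and 2 both had 0.944, against 0.964 to 0.966, and weights of 0.286 and 0.337.

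A hypothesis is that a higher deposited value is more lung RNA than reference RNA. A lung signal near its floor can then move only toward 0, so called probes under -3 would move away from 0 less often than those over 3. For the explanation that a higher value is more lung RNA than reference RNA, this held at 7 of 7 times, with 2.21% against 13.8% at 1 week, but at 8 weeks only with 4.90% against 6.94%, or 5 probes at each end. The result may point to that direction without settling it.

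Chance was examined for the other counts by splitting the samples anew, 100 splits each. At each of the 7 times 1 split, the real one, gave as many probes. A share of 1 in 100 is the smallest these splits allow, and it was not adjusted over the counts examined. The real counts and the highest others were 9944 and 5886 at 3 days, 8568 and 4167 at 1 week, 5795 and 4289 at 2 weeks, 1156 and 74 at 3 weeks, 3681 and 2499 at 4 weeks, 962 and 78 at 6 weeks, and 2124 and 816 at 8 weeks. For the mean effect it was 1 split too, with 15324 and 4420. For vehicle against untreated, 3 of 56 splits gave as many as the 795 probes called, with 1146 in the highest other, so chance is not excluded.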
